A study of Drosophila melanogaster with 3 samples.

How the data were processed

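The deposited files are peak lists from anti-GFP ChIP-seq on 3 libraries of whole white prepupae with topi-eGFP. Chromatin was fragmented by sonication, per the labels, with fragments of 200 to 800 bp selected. Per the text files deposited with the samples, the authors aligned reads to the dm6 and dm3 builds, called relaxed peaks in each replicate and in the pool of the 3 replicates against a control alignment, and derived from these lists an optimal IDR-thresholded set. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The control library and the read-level files were not used here. All replicates share 1 control alignment.

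The deposited lists follow the narrowPeak layout. The signal value of each peak is the authors' enrichment score against the control, not scaled between libraries, and was used only to rank, filter or describe peaks within a list or, for correlations, by rank and log2 value across peaks. The deposited -log10 q-value was the same for all peaks of the IDR set (4.28 in dm6) and was not used to filter. The summit is the offset the authors' caller gave, written here as a 1-based position. The relaxed lists stop at 30000 peaks, so the absence of a peak means only that none reached that rank. The pooled relaxed list is labelled as peaks and background for IDR, so it includes background regions. In dm6 its -log10 q-value went down to 0.186. Each build has 5 lists. The dm6 lists were the main data. The dm3 lists (8178 IDR peaks) served as an alternative, and no coordinate was converted. In dm6, 100 IDR peaks repeat the interval of another IDR peak listed before them, as further summits of 1 region, and were kept. Depth per sample is unknown, since peak lists hold no read counts, so no limit of detection is given.

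Genes, TSSs, exons and untranslated regions came from the Ensembl release 115 annotation of the same assembly, whose chromosome lengths hold all dm6 peaks. It gave 18277 genes and 24111 TSSs on the main chromosomes after transposable elements were left out. A peak counted as promoter-proximal with its summit within 500 bp of a TSS of any gene, and a gene counted as occupied with an IDR summit within 500 bp of any of its own TSSs. Symbols of the fixed lists were matched directly or by listed synonyms, and 4 list members were not analysed here. Some annotation matches are loose: Cds and Cpr entered lists through a synonym and a symbol pattern.

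Peaks counted as shared when they overlapped by at least 50% of either peak. Support was counted against the 8424 strongest peaks of each replicate, with 1000 random placements on the same chromosomes. Shares of peaks and genes were compared with two-sided Fisher's exact tests, given as log2 odds ratios with 95% intervals, and where a count was 0 no odds ratio is quoted. Stratified comparisons used the Mantel-Haenszel estimate with a Cochran-Mantel-Haenszel p, over 5% bins of GC content, the outermost bins open-ended, or over 5 classes of the number of TSSs per gene. The difference between distal and promoter peaks on X was tested with a normal approximation of the log odds ratios. Adjusted p-values are Benjamini-Hochberg values over the lists, chromosomes or motif tests named beside them. Motifs were searched on both strands within 100 bp of the summit. Uniqueness was the share of 32-mers found once on the main chromosomes, within 250 bp of a TSS or 400 bp of a summit. Bounds of upstream shares are exact Clopper-Pearson intervals, which cover counting error only.

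The rule for named genes took topi, the gene of the closest TSS for those of the 20 strongest IDR peaks with a summit within 500 bp of it, the 10 strongest peaks over 500 bp from any TSS with the gene they lie in, up to 4 members per list by the signal of their strongest IDR peak, and all tMAC and testis-specific TAF members. This rule, the gene lists, the motifs and the tests of the report were fixed before the data were examined, except where a sentence says otherwise. Other genes named (twe, bol, Mst87F, the last 4 dREAM members, RpS29, CG9471, Whamy and members of added groups) were chosen after their values were seen. Alternatives included other TSS and motif windows, other overlap rules, stricter peak sets, other backgrounds, dm3, and leaving out each replicate in turn, for which IDR peaks supported by the other 2 replicates were used. No samples were left out.

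Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. For the gene list test, 400 simulated sets of 60 among 13000 genes gave a call in 5.2% of cases with no planted difference. With a planted log2 odds ratio of -2 the share was 95.5%. A call here was an unadjusted p under 0.05, and shorter lists were not simulated. For the GC-stratified test, 100 simulations with no planted difference gave a median log2 odds ratio of -0.003, against -0.83 without strata. For the 6-mer scan, a 6-mer planted in 10% of the simulated peaks ranked 1 in a single simulation. Both simulated sets had the same base composition, so neither a GC difference between sets nor smaller effects were covered.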

Results

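Topi (matotopetli) is a zinc-finger protein of the testis-specific meiotic arrest complex (tMAC), which turns on genes of spermatocytes. Its binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole white prepupae of Drosophila melanogaster, both sexes together, from a line that carries topi fused at its C terminus to eGFP. An anti-GFP antibody was used. The series holds 3 libraries of 1 group, replicates 1 to 3, and no second condition, so the comparisons are between peak sets, gene groups and replicates. None of the libraries is from animals without the tag, so peaks that do not depend on topi cannot be told apart from topi binding. Nothing in the labels says that the replicates came from separate collections of animals beyond their biological replicate numbers. Each replicate and the pool of all 3 had a relaxed list of 30000 peaks. The set that passed the irreproducible discovery rate (IDR) threshold held 8424 peaks in the dm6 build. Peak lists give no read counts, so the depth of each library is unknown. Median peak signal in the relaxed lists was 10.98 in replicate 1, 22.3 in replicate 2 and 22.5 in replicate 3, in the authors' units, which are not scaled between libraries. Throughout, relaxed-only peaks are the 20304 pooled relaxed peaks that shared less than 50% of either peak's length with every IDR peak. By the label of the pooled list, some of them may be background. Tests over peaks or genes treat these as independent, which neighbouring peaks and genes need not be.

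The first question was where the anti-GFP signal was strongest. The strongest IDR peak lay at the promoter of Ugalt, which encodes a UDP-galactose transporter, and had rank 1 in each of the 3 replicates. The next strongest peaks lay at CG14100, in CG11050, near cbt and at PNPase, which encodes an RNA exonuclease of mitochondria. Of the 20 strongest peaks, 12 had their summit within 500 bp of a transcription start site (TSS), and the other 8 lay in introns, a non-coding exon or between genes. All 20 were found among the strongest 8424 peaks of every replicate, with no replicate rank beyond 32.

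The Ugalt peak (X, 2703654 to 2704127 in dm6, summit 2703886) lay 34 bp from the TSS of Ugalt (FBgn0024994), outside its transcribed region. Its pooled signal was 4484, and its signal was 1183 in replicate 1, 1453 in replicate 2 and 1879 in replicate 3. The CG14100 peak (FBgn0036889; 3L, 19590379 to 19590866) had a pooled signal of 4026 and ranked 2, 3 and 2 in replicates 1, 2 and 3. The PNPase peak (3R, 31404440 to 31404895) lay 81 bp from the TSS, with a pooled signal of 3645. Chro, which encodes the chromosome and spindle-matrix protein Chromator, had a peak (3L, 22878664 to 22879149) with a pooled signal of 3196. The remaining promoters among the 20 strongest peaks were those of CG1888, CG18549, CenG1A, CG9147, Art3, Tcs5, larp and mRpL41, with pooled signals from 3026 down to 2646. Art3 encodes an arginine methyltransferase, larp an RNA-binding protein, and mRpL41 a protein of the mitochondrial ribosome.

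The strongest peak over 500 bp from any TSS lay in an intron of CG11050 (2L, 6612388 to 6612972), with a pooled signal of 3692 and ranks of 9, 2 and 3 in replicates 1, 2 and 3. The next lay in an intron of ush (2L, 480555 to 481339), which encodes a GATA cofactor, 1370 bp from the TSS of cbt, with a signal of 3682. Introns of Lk6 (3R, 11760789 to 11761355), CG32772 (X, 4910163 to 4910707) and CG32486 (3L, 3060577 to 3061028) had signals of 3535, 3161 and 2601. A peak in the non-coding RNA gene CR46035, itself inside osa (3R, 17704188 to 17704661), had a signal of 3050. Summits between genes lay at 2L 2202413, with CG31668 as the closest TSS at 3753 bp, and at 2R 13035326, with CG13323 closest at 11930 bp. Their signals were 2903 and 2761. The peak in the non-coding RNA gene Vinr (X, summit 12751360) had a signal of 2562. The last of the 10 strongest such peaks lay in an intron of Eip75B (3L, 18011642 to 18012134), an ecdysone-induced nuclear receptor gene, with a signal of 2424 and ranks of 31, 23 and 25.

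The next question was whether the replicates held the same sites. Replicate 1 held 82.1% of the IDR peaks among its own strongest 8424 peaks, replicate 2 held 84.0% and replicate 3 held 89.3%, a mean of 85.2% ± 3.75 (SD, n = 3). All 3 replicates shared 5563 IDR peaks, or 66.0%, and 48 IDR peaks were in none of the 3 strongest sets. Randomly placed peaks on the same chromosomes covered on average 2.51% to 2.59% of the IDR peaks per replicate. The one-sided randomization p was 0.001 for each replicate and for all 3 together, the smallest that 1000 placements can give. Support fell with signal. Among the strongest 843 IDR peaks it was 99.4% in replicate 1 and 100% in replicates 2 and 3, and among the weakest 842 it was 51.3%, 43.2% and 49.2%. Across IDR peaks, which are not independent replicates, the Spearman correlation of replicate signals was 0.75 for replicates 1 and 2, 0.84 for replicates 1 and 3, and 0.81 for replicates 2 and 3. The IDR set was itself chosen on these replicates, so this support is not an independent check.

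**Figure D1:**
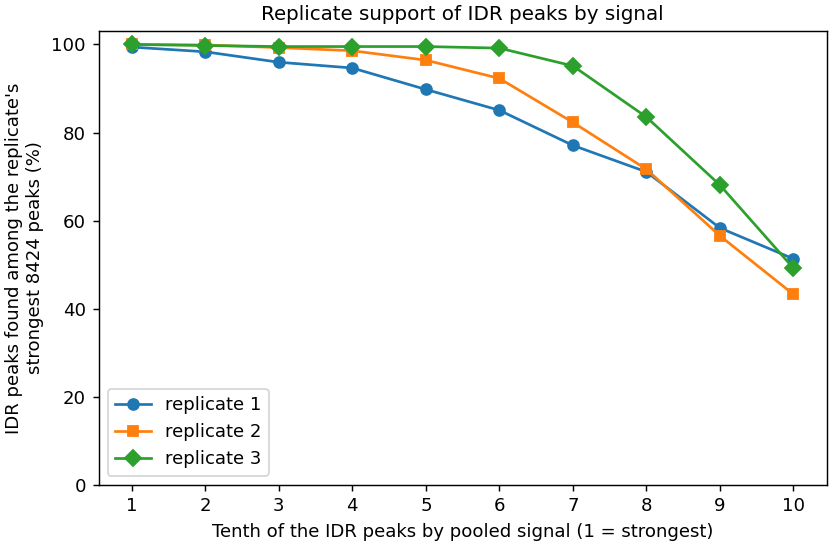
The x axis splits the 8424 IDR peaks by pooled signal into 10 classes of 842 or 843 peaks, strongest first, and the y axis gives the percent found among each replicate's strongest 8424 peaks; each line is 1 replicate. Support starts at 99.4% or more and ends between 43.2% and 51.3%.

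IDR peaks lay at promoters more often than weaker peaks did. Of the 8424 IDR summits, 3307 (39.3%) lay within 500 bp of a TSS, against 22.9% of relaxed-only summits and 13.7% of random positions on the same chromosomes. The log2 odds ratio against relaxed-only peaks was 1.12 (95% interval 1.04 to 1.20, Fisher's exact test, two-sided, p = 2.99e-169). In the replicates' own lists, 40.2% ± 5.08 (SD, n = 3) of the strongest 8424 summits were within 500 bp of a TSS, against 24.1% ± 5.76 of the rest, and the share was higher among the strongest in 3 of 3 replicates. Promoter summits sat mostly upstream of the TSS, with a median of -95 bp and quartiles of -196 and 0 bp relative to transcription. Introns held 41.0% of IDR summits and 46.4% of relaxed-only summits. Intergenic DNA held 17.3% and 25.1%. Coding exons held only 14 IDR summits (0.166%), against 1.25% of relaxed-only summits and 13.02% of random positions. The strongest 2106 IDR peaks were promoter peaks in 42.5% of cases and the weakest 2106 in 38.0% (log2 odds ratio 0.27, interval 0.09 to 0.45, Fisher's exact test, p = 0.00314). This last difference was lost without replicate 1, among the IDR peaks supported by replicates 2 and 3, where the log2 odds ratio was 0.01 (Fisher's exact test, p = 0.972). Without replicate 2 the log2 odds ratio was larger, at 0.83, and without replicate 3 it was 0.78.

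**Figure D2:**
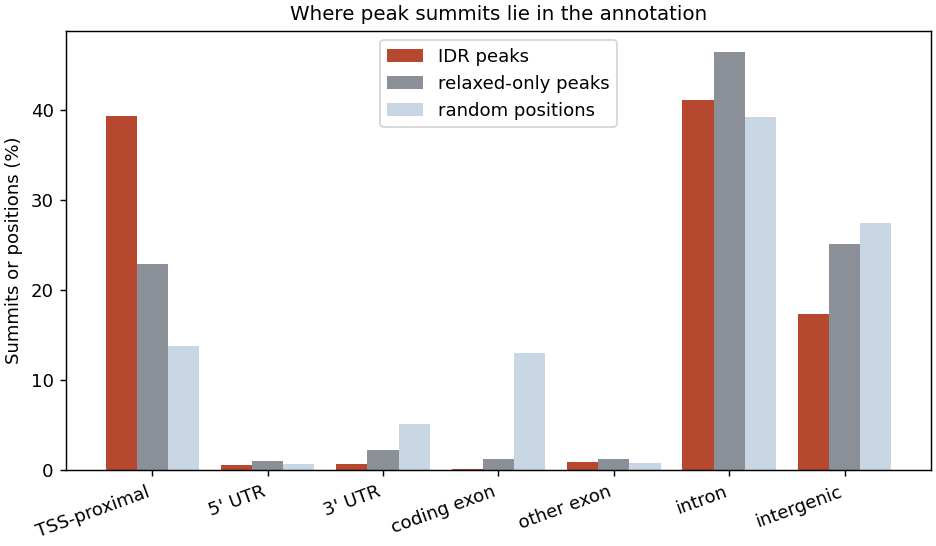
Bars give the percent of summits or random positions (y axis) in each annotation class (x axis) for IDR peaks, relaxed-only peaks and random positions on the same chromosomes. Promoters held 39.3% of IDR summits against 22.9% and 13.7%, and coding exons held 0.166% against 1.25% and 13.02%.

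By chromosome, IDR peaks were enriched on X and scarce on chromosome 4. X held 1701 IDR peaks (20.2%, or 72.3 per Mb) against 18.1% of relaxed-only peaks, a log2 odds ratio of 0.20 (interval 0.10 to 0.29, Fisher's exact test, Benjamini-Hochberg adjusted p over 6 chromosomes 0.000121). Chromosome 4 held 26 IDR peaks, or 19.3 per Mb, with a log2 odds ratio of -1.86 (interval -2.45 to -1.28, adjusted exact p = 2.85e-12). Against protein-coding genes in place of relaxed-only peaks it was -0.90 (adjusted exact p = 0.00671). The arms 2L, 2R, 3L and 3R had between 57.1 and 64.6 peaks per Mb and did not pass the test. The X difference was uneven between replicates. Comparing the strongest 8424 peaks of each replicate with the rest of its list, a test chosen after the data were seen, gave log2 odds ratios of 0.38 in replicate 1, 0.10 in replicate 3 and 0.07 in replicate 2, where the exact p was 0.149. No peak was listed on Y, which the dm6 lists do not name.

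The tagged protein is a testis factor, so gene groups of the testis and of the prepupa were compared with all other genes. The genes of spermatogenesis were almost free of IDR peaks, and ribosomal protein genes carried them most often. Of 13968 protein-coding genes, 3391 (24.3%) had an IDR summit within 500 bp of a TSS. Of 18 fixed gene lists, 3 were higher than other genes and 5 were lower at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg over the 18 lists). Of the 61 spermatogenesis genes, 2 had a peak (3.28%, against 24.4% of other genes; log2 odds ratio -3.25, interval -5.28 to -1.21, adjusted exact p = 6.84e-05). These were Cds, a CDP-diglyceride synthase gene that entered the list through an older symbol, and Pif1A, with pooled signals of 345 and 128; replicate 1 listed no peak at Pif1A. Per replicate the share was 3.28% ± 1.64 (SD, n = 3), against 24.97% ± 2.73 for all protein-coding genes. Of the 59 members without an IDR peak, only 9 had a relaxed-only summit within 500 bp of a TSS. Among these were twe, bol and Mst87F, whose strongest pooled peaks near a TSS had ranks 16776, 14950 and 10324.

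The lists of the complex itself and of the testis-specific TAFs did not differ from other genes past the threshold. Both lists are small, so the lack of a call says little about them. With 5 TAF genes, even a count of 0 gave an unadjusted exact p of 0.345, so no lower share could have passed. Of 9 tMAC genes only mip40, which encodes a subunit shared with the somatic dREAM complex, had an IDR peak (2R, 19292000 to 19292429), with a pooled signal of 99.7 and ranks of 2810, 26418 and 10469 in replicates 1, 2 and 3. The others, topi, comr, aly, tomb, wuc, achi, vis and Caf1-55, had no summit of the pooled lists within 500 bp of a TSS (adjusted exact p = 0.738 for the list). None of the 5 testis-specific TAF genes, can, sa, mia, nht and Taf12L, had an IDR peak (adjusted exact p = 0.443), and nht had a relaxed peak at rank 28793. The 12 Y-linked fertility genes had none (adjusted exact p = 0.0778), on a chromosome with no listed peaks.

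Ribosomal protein genes had an IDR peak in 75 of 92 cases (81.5%; log2 odds ratio 3.81, interval 3.05 to 4.57, adjusted exact p = 1.09e-29), with 78.6% ± 5.47 (SD, n = 3) per replicate. The strongest were at RpS27, RpL32, RpL7 and RpL14, with pooled signals of 795, 781, 770 and 578. Of the 11 dREAM genes, which encode a somatic cell-cycle repressor complex, 8 had a peak (log2 odds ratio 3.06, interval 1.14 to 4.97, adjusted exact p = 0.00345). Dp, Rbf2, mip130 and l(3)mbt had signals of 740, 360, 278 and 133, and Rbf, E2f2, Myb and mip40 had weaker ones. The last 4 ranked between 6941 and 7943 of 8424. The dREAM call was lost among the strongest 4212 IDR peaks (log2 odds ratio 1.21, adjusted exact p = 0.344), with a TSS window of 200 bp (1.97, p = 0.0908), among peaks of all replicates (1.63, p = 0.176) and without replicate 1 (1.19, p = 0.331) or 3 (1.57, p = 0.175). Of 35 ecdysone response genes, 17 had a peak (48.6%; log2 odds ratio 1.56, interval 0.61 to 2.52, adjusted exact p = 0.00674), led by hid, Eip75B, Hr3 and ImpE3 with signals of 1044, 957, 907 and 358. This call was lost when genes were matched on their number of TSSs (log2 odds ratio 0.89, adjusted p = 0.158, n = 35 genes). It was also lost with the 200 bp window (1.30, adjusted exact p = 0.0512), among the strongest 4212 peaks (1.30, p = 0.0853), among peaks of all replicates (1.12, p = 0.155) and without replicate 2 (1.15, p = 0.0884) or 3 (1.05, p = 0.14).

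Cuticle protein genes had an IDR peak in 1 of 91 cases (log2 odds ratio -4.86, interval -7.71 to -2.02, adjusted exact p = 3.57e-09). That gene, Cpr, encodes cytochrome P450 reductase and entered by its symbol. With a TSS window of 1000 bp the log2 odds ratio was -2.25 (adjusted exact p = 1.07e-05). Homeotic genes and Polycomb targets had a peak in 1 of 30 cases, at Dll with a signal of 234 (log2 odds ratio -3.22, interval -6.10 to -0.34, adjusted exact p = 0.0116), although replicate 2 alone gave 13.3% and replicate 1 none. By a count chosen after the data were seen, 20 of the other 29 had a relaxed-only summit within 500 bp of a TSS (69.0%, against 23.8% of other genes without an IDR summit), so the lower share holds for IDR peaks only. The 20 glue and late puff genes of the salivary gland had no IDR peak (adjusted exact p = 0.0155). By the same later count, 6 of the 20 had a relaxed-only summit (30.0%, against 23.9% of other genes without an IDR summit). Among the strongest 4212 peaks the calls of the last 2 lists were lost, with an adjusted exact p of 0.254 for each, and without replicate 1 both had 0.0552. The log2 odds ratios of the homeotic and Polycomb list were then -2.24 and -2.87. With the 200 bp window its value was -2.63 (adjusted exact p = 0.112). The glue and puff genes then had an adjusted exact p of 0.0932. With 0 genes with a peak, the glue and puff list has no odds ratio to quote. The call of the glue and puff genes was also lost among peaks of all replicates (adjusted exact p = 0.155), without replicate 2 or 3 and when matched on the number of TSSs. The 111 histone genes also had no peak (adjusted exact p = 4.10e-13), but none of them had TSS windows with at least 90% unique 32-mers, so the value is uncertain.

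The other lists did not pass the test. Heat shock genes had peaks in 8 of 18 cases (adjusted exact p = 0.0829), and Hsp27 held the strongest of all list members with a signal of 2432, ahead of Hsp26, Hsp83 and stv at 742, 660 and 579. Over the 13 heat shock genes with unique TSS windows, a restriction chosen after the data were seen, 8 had a peak (adjusted exact p = 0.014). Signalling genes had 13 of 31 (adjusted exact p = 0.0599), led by spi, E(spl)m7-HLH, aos and pnt with signals of 1070, 665, 330 and 180. Replicate 2 gave 61.3% for this list and replicate 1 gave 25.8%, and with a TSS window of 1000 bp it passed the test (log2 odds ratio 2.22, adjusted exact p = 9.81e-05). Cell-cycle genes had 12 of 34 (adjusted exact p = 0.22), including RnrS, aurA, Cdk1 and Mcm2. Germline genes had 6 of 19 (adjusted exact p = 0.499), including orb, bgcn, bcd and piwi. Neuronal genes had 4 of 18 (adjusted exact p = 1), with elav at a signal of 1120 and futsch, Syx1A and Csp under 200. Muscle genes had 3 of 21, at Tm1, sls and Mef2 (adjusted exact p = 0.499), and fat body genes 0 of 14 (adjusted exact p = 0.0577). Matched on the number of TSSs, muscle genes (adjusted p = 0.0377, n = 21 genes) and fat body genes (adjusted p = 0.0337, n = 14 genes) passed as lower.

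**Figure D3:**
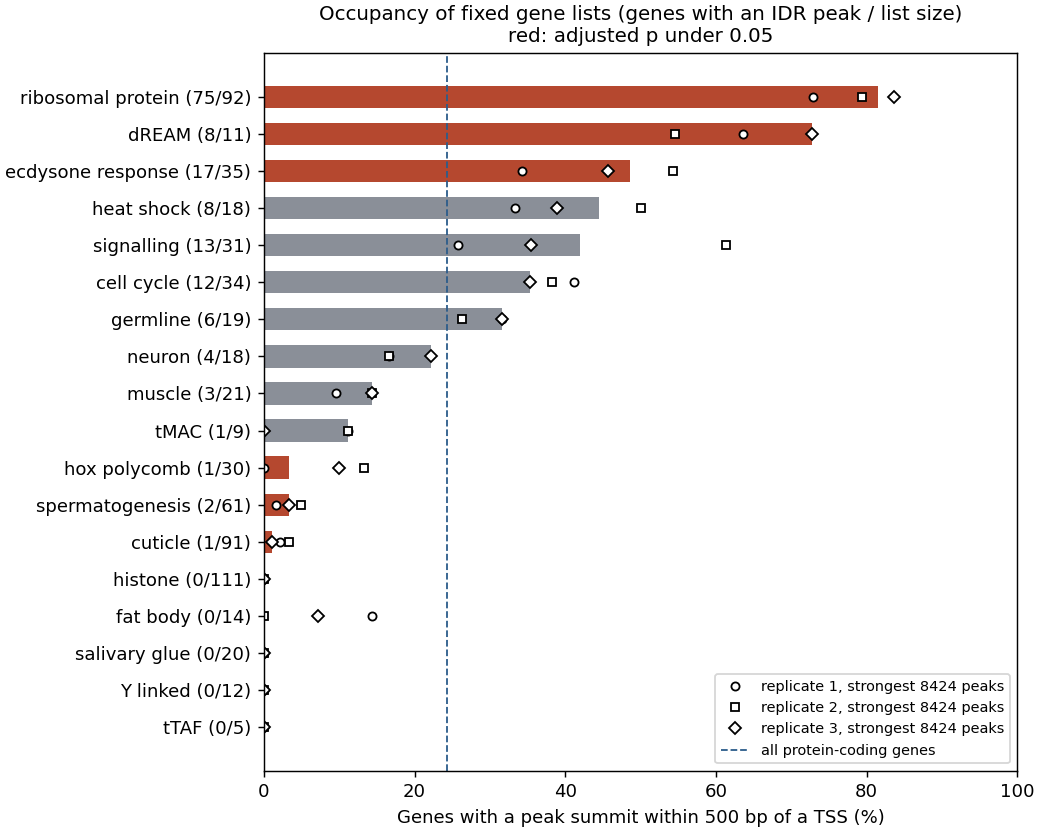
Bars give the percent of each list's genes (x axis) with an IDR summit within 500 bp of a TSS, with counts beside the list names (y axis); open symbols give the same share for each replicate's strongest 8424 peaks, the dashed line is the 24.3% of all protein-coding genes, and red marks adjusted p under 0.05. Histone and salivary glue genes also passed, with bars of 0. Ribosomal protein genes reach 81.5%, and spermatogenesis genes stay at 3.28%.

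At the tagged gene itself, topi (FBgn0037751; 3R, 9775121 to 9777943, plus strand), no IDR peak and no pooled relaxed peak had its summit inside the gene. Within 20 kb of it were 8 IDR summits, against a median of 3 in windows of the same size around protein-coding genes, and 9.25% of those windows held at least as many. The strongest (3R, 9771435 to 9771971, summit 9771629) lay 3492 bp upstream of topi, between CG9471 and Whamy, with a pooled signal of 1709 and rank 69. It ranked 104, 46 and 76 in replicates 1, 2 and 3. The closest summit, at 9778083, lay 140 bp past the end of topi and inside the ribosomal protein gene RpS29, with a signal of 317. The closest upstream summit, at 9774463, was 658 bp from topi, with a signal of 108 and rank 7347, and replicate 1 listed no peak there. The tagged gene is carried as a transgene, so extra DNA copies can enrich this locus. Whether they add to these summits was not tested.

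**Figure D4:**
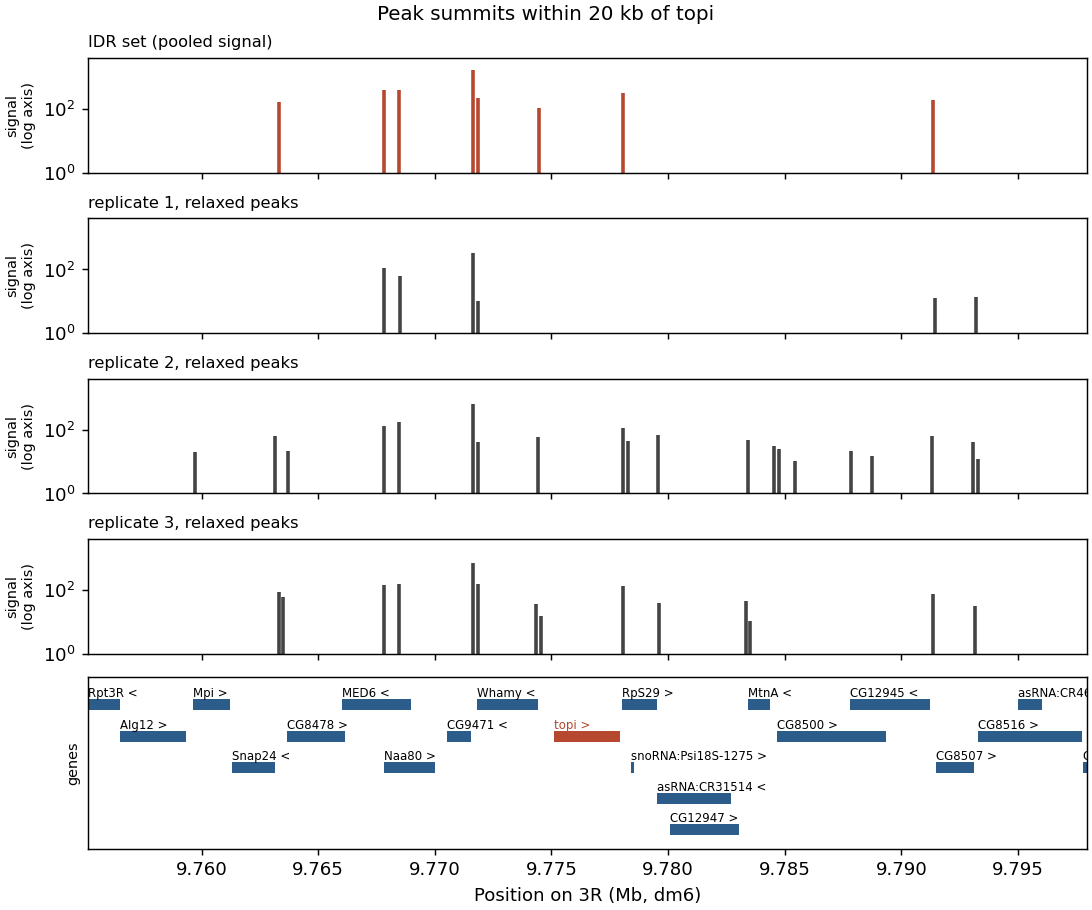
Vertical lines mark peak summits within 20 kb of topi on 3R (x axis, Mb in dm6) with their signal (y axis, log scale) in the IDR set and in each replicate's relaxed list; gene bars below carry arrows for strand, with topi in red. The summit at 9771629, with a pooled signal of 1709, is the highest in every panel.

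Sequence was compared within 100 bp of the summits, at promoter peaks and distal peaks separately, for 17 fixed motifs. IDR summits were richer in A and T than relaxed-only summits, with a GC content of 35.5% against 38.5%, and in the replicates' lists 35.7% ± 1.09 against 39.4% ± 0.52 (SD, n = 3). Without regard to this, 6 motifs were more frequent and 3 less frequent at promoter IDR peaks, and 3 were more and 4 less frequent at distal ones (Fisher's exact test, adjusted over 34 tests). With peaks stratified by GC content, 2 were more frequent at promoters and 1 at distal peaks, and none was less frequent. At promoters these were core promoter motif 7 (16.3% of IDR against 10.9% of relaxed-only peaks; GC-stratified log2 odds ratio 0.75, interval 0.55 to 0.94) and the DREF site TATCGATA (6.02% against 3.96%; 0.47, interval 0.18 to 0.77). Without GC strata, the DREF site call was lost among the strongest 4212 peaks (log2 odds ratio 0.25, adjusted exact p = 0.384) and without replicate 3 (0.40, adjusted exact p = 0.0564). At distal peaks the motif more frequent after stratification was GAGAG (22.0% against 21.1%; 0.39, interval 0.27 to 0.50), which did not pass without strata (0.08, interval -0.03 to 0.19, adjusted exact p = 0.219). The CHR-like sequence TTTGAA, bound by the LIN54 family to which the tMAC subunit tombola belongs, was present at 31.8% of distal IDR peaks and 25.8% of distal relaxed-only peaks (log2 odds ratio 0.42, adjusted exact p = 8.40e-15). Its GC-stratified log2 odds ratio was 0.12 (interval 0.02 to 0.22, adjusted p = 0.14, n = 5117 IDR peaks), at promoters it went from 0.33 to 0.02, and 20 of the 60 6-mers made of the same bases, itself included, had a distal value as high. TGACAG, the site type of achi and vis, was less frequent at distal IDR peaks (5.47% against 7.01%; log2 odds ratio -0.38, adjusted exact p = 0.000289). GC stratification ended this call (-0.21, adjusted p = 0.169, n = 5117). The E2F-type site was also less frequent, with -0.72 at distal peaks, and -0.23 (adjusted p = 0.169, n = 5117) after stratification.

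A scan of all 2080 6-mers took the 10 with the lowest p on 2L, 2R and X to a test on 3L and 3R. All 10 passed (adjusted exact p from 7.58e-35 to 2.57e-08), and most were strings of A and T such as TTAAAA and TTTAAA. The exceptions were ACAGTG (15.8% of IDR against 10.2% of relaxed-only peaks on 3L and 3R; log2 odds ratio 0.72, adjusted exact p = 3.88e-18), ACACTG (17.1% against 11.3%; 0.69) and GGCCAA, which was less frequent (7.45% against 11.8%; -0.73). With a GC-stratified background, added after the data were seen, ACAGTG and ACACTG had the lowest p in the scan, with log2 odds ratios of 0.76 and 0.68 on 3L and 3R, where CGATAG had a larger one of 0.82. All 10 6-mers taken to the test passed, of which only ACAGTG and ACACTG were among the 10 of the first scan. Sequence on all arms had been looked at before this scan was extended, so for the choice of ACAGTG and ACACTG 3L and 3R are not unseen data. In the replicates' own lists, ACAGTG was near 16.8% ± 0.31 of the strongest 8424 summits and 10.9% ± 0.09 of the rest (SD, n = 3), higher in 3 of 3 replicates. Its position was then examined, after profiles of several sequences had been seen. Read on its own strand, ACAGTG occurred 79.4 times per 1000 IDR peaks at 80 to 120 bp upstream of the summit and 28.6 times at 80 to 120 bp downstream. In the strongest 2106 peaks these values were 134 and 30.9, and in relaxed-only peaks 28.6 and 20.9. GC content was lowest within 40 bp of IDR summits, at 33.4%, and was 44.4% at 360 to 400 bp.

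**Figure D5:**
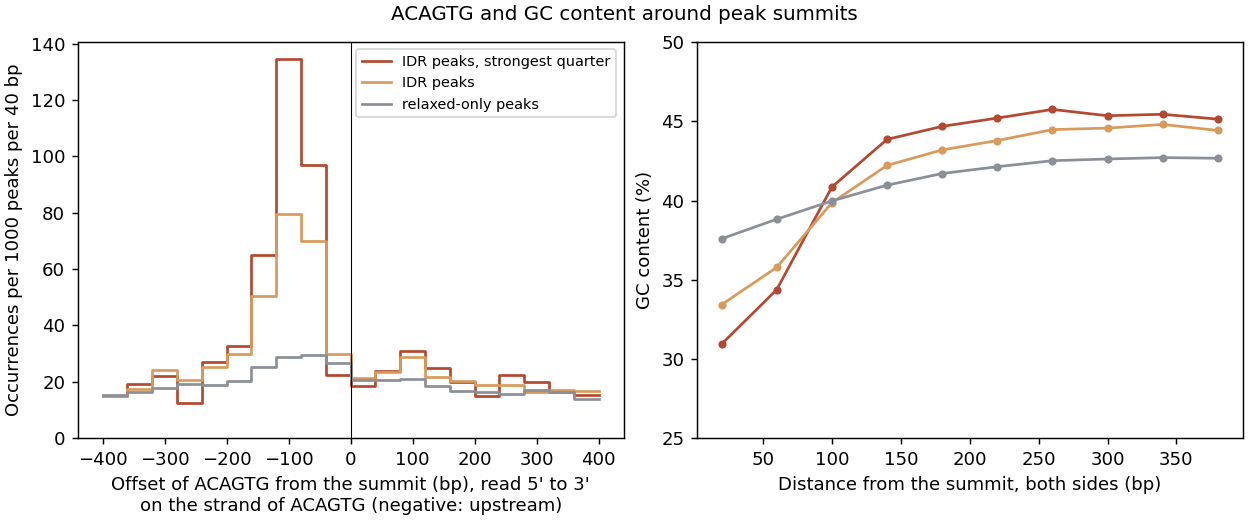
Left, occurrences of ACAGTG per 1000 peaks in 40-bp bins (y axis) by offset from the summit in bp, read on the strand of ACAGTG (x axis); right, GC content in percent (y axis) by distance from the summit in bp (x axis), for the strongest 2106 IDR peaks, all IDR peaks and relaxed-only peaks. ACAGTG reaches 134 per 1000 upstream of the strongest summits, and GC content falls to 30.9% within 40 bp of them.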

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

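The tests on X by position and by replicate were chosen only after the result was seen, and the patterns themselves came from the data.

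The dm3 IDR set held 5 peaks on heterochromatin scaffolds, listed here because dm3 was used only as an alternative. The dm6 lists name only the main chromosomes, and whether they hold the same sites under those names was not tested, so the count shows no excess over dm6. They lay on 3LHet (3 peaks) and XHet (2 peaks), and the strongest, at XHet 49924 to 50353, had a signal of 175 and rank 4292 of 8178.

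Few IDR peaks at spermatogenesis genes were seen in a sample that holds testes among all other tissues. A low share was not particular to this list. Cuticle genes had a peak in 1 of 91 cases, and the later added odorant and gustatory receptors in 0 of 59 and 0 of 60. Neuronal genes, with 4 of 18, and germline genes, with 6 of 19, did not differ from other genes past the threshold. Annotation argues little: matched on the number of TSSs, the log2 odds ratio was -3.72 (interval -6.03 to -1.41), so the number of TSSs is not the whole cause. Over genes with unique TSS windows it was -3.1 (interval -5.14 to -1.06), which argues against reads lost to near-identical copies. Dilution of testis chromatin by other tissues stays open: among genes without an IDR peak, 9 of 59 list members and 23.9% of other genes had a relaxed-only summit, a log2 odds ratio of -0.806 whose interval (-1.83 to 0.22) allows either direction. No biological explanation was tested, since the design has 1 group.

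More IDR peaks on X were seen than relaxed-only peaks led to expect. A larger number of genes on X does not account for them, since against protein-coding genes the log2 odds ratio was 0.44 (interval 0.34 to 0.54). Distal peaks need not follow the number of genes, so this comparison cannot tell whether sparser genes play a part. Among peaks with neither GAGAG nor ACACACAC it was 0.201 (interval 0.09 to 0.31), so those repeats are not the whole cause. The enrichment was 0.28 at distal peaks and 0.07 at promoters (difference 0.21, interval 0.01 to 0.41, p = 0.0397, n = 8424 IDR peaks). Replicate 1 alone gave 0.38, replicate 2 only 0.07, and neither what sets replicate 1 apart nor any biological explanation was tested.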

How the results depend on the processing

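The per-replicate values for X, the GC-stratified 6-mer scan and the spermatogenesis and cuticle lists without their members with a peak were chosen only after the data were seen. Of 108 alternative values of the main results, 83 kept their direction and their side of the threshold or, for counts and shares, their range, as did 198 of 258 for single lists and motifs. Among these 258 are the 2 lists without their members with a peak, whose outcome was fixed by that choice and shows no stability. The values of 2 other lists also had little room to move. Histone genes had no unique TSS windows and no relaxed-only summits, and the 5 testis-specific TAF genes were too few to pass as lower. The promoter share stayed past its threshold throughout, from 0.90 without replicate 2 to 1.21 without replicate 1, as did chromosome 4 and, under the alternatives fixed beforehand, the ribosomal, spermatogenesis and cuticle lists. Library depth is unknown, so what it limits could not be weighed. Unless a cause is named, the cause was not tested.

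The share of IDR peaks found in all replicates (66.0%) was 59.57 with summits within 100 bp and 90.53 with all relaxed peaks, which are a longer list; without a replicate it ran from 69.68 to 76.83, since fewer replicates had to agree. Against protein-coding genes, 2R turned to -0.3106 and 3L to 0.171, both past the threshold (adjusted exact p = 4.67e-09 and 0.000882), and 2L (-0.1098) and 3R (-0.1242) passed it too. 2R passed in dm3 (0.1244) and ran from 0.05806 to 0.1342 without a replicate, passing without replicate 1. X in replicate 2 alone was 0.06944. The promoter share of strong against weak peaks ran from 0.007263 without replicate 1 to 0.8252 without replicate 2.

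Lists higher than other genes (3) were 1 with a 200 bp window, 1 with the strongest 4212 peaks and 1 with peaks of all replicates, and from 1 to 2 without a replicate, with 1 left without replicate 3. Lists lower (5) were 3 with the 200 bp window and 3 with the strongest 4212 peaks, and from 3 to 4 without a replicate. Smaller sets hold fewer peaks to test. With the 1000 bp window 4 were higher and 7 lower, with Y-linked (adjusted exact p = 0.0409) and fat body genes (0.0269) among the lower, and matched on the number of TSSs 6 were lower. Signs turned, none past the threshold, for signalling with the strongest 4212 peaks (-0.1358), neurons with peaks of all replicates (0.1131) or without a replicate (from -0.3271 to 0.04971) and germline genes at 200 bp (-0.1851).

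Stratified by GC content, motifs higher at promoters fell from 6 to 2 and lower ones from 3 to 0. At distal peaks the 3 higher ones, TTTGAA, TATA and GATA, all lost their call, 1 other (GAGAG) gained one, and lower ones fell from 4 to 0. With 200 bp around the summit, lower ones were 1 at promoters and 1 at distal peaks. GC strata turned the sign of GAGAG (0.03363) and GATA (-0.04721) at promoters and TATA (-0.08888) at distal peaks, and the strongest 4212 peaks that of the BEAF site at promoters (-0.03468).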

Other observations

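The gene families, the counts of relaxed-only summits and the position tests of ACAGTG and ACACTG were chosen only after the data were seen. Profiles of other sequences, among them CGATAG, TTTAAA, TTTGAA, CAGCTG, GAGAG, TATCGATA and TTGGCC, were looked at too, and ACAGTG and ACACTG were carried on for what theirs showed.

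Mitochondrial ribosomal protein genes also carried IDR peaks more often than other genes, at 33 of 73 (45.2% against 24.2%; log2 odds ratio 1.37, interval 0.70 to 2.04, Fisher's exact test, adjusted p over 14 added families = 0.000259). The promoters of mRpS23, mRpS10 and mRpL41 were among the 20 strongest peaks, with signals of 2890, 2671 and 2646, the first 2 at peaks shared with the neighbouring genes CenG1A and Art3. Chemosensory receptor genes were almost without peaks, at 0 of 59 odorant, 0 of 60 gustatory and 1 of 60 ionotropic receptors. Their adjusted exact p-values were 8.07e-07, 8.07e-07 and 1.06e-05. Seminal fluid protein genes had 1 of 47 (adjusted exact p = 0.00018) and cytochrome P450 genes 10 of 85 (adjusted exact p = 0.0102). Proteasome, translation initiation, tRNA synthetase, complex I, coatomer, tubulin and actin, and Enhancer of split genes did not differ from other genes past the threshold, and odorant-binding proteins had 2 of 51 (adjusted exact p = 0.000486).

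Homeotic and Polycomb target genes, with 1 IDR peak among 30, often had a relaxed-only summit. Of the 29 without an IDR summit, 20 had a relaxed-only summit within 500 bp of a TSS (69.0% against 23.8% of other such genes; log2 odds ratio 2.83, interval 1.70 to 3.97, adjusted exact p = 3.13e-06). Matched on the number of TSSs it was 2.41 (adjusted p = 8.97e-05, n = 29 genes). These 20 genes ranked from 8527 (Dfd) to 28776 (pb) in the pooled list of 30000. Only Dfd, ap, Antp and ems, up to rank 10266, lay ahead of rank 11393 (tsh). The summit at pb had a signal of 19.6, near the list's minimum of 18.4. Summits this low may be background. Among signalling genes without an IDR summit, a relaxed-only summit was also more frequent than among other such genes, at 12 of 18 (log2 odds ratio 2.68, adjusted exact p = 0.000858), among them ptc, rho and dpp. Ecdysone response genes had 10 of 18 (log2 odds ratio 2.00, adjusted exact p = 0.017). How many genes of these lists count as occupied therefore depends on how far down the pooled list peaks are counted, and at spermatogenesis genes the share with a relaxed-only summit was 15.3%.

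ACAGTG lay upstream of the summit on its own strand. Of IDR peaks with it on a single side within 160 bp, 1403 had it upstream and 623 downstream (69.2% upstream, interval 67.2 to 71.3), rising to 75.1% in the strongest 2106 peaks, against 56.7% in relaxed-only peaks. The replicates' strongest 8424 peaks gave 67.8% ± 1.85 (SD, n = 3) and the rest of their lists 55.1% ± 0.69, and ACACTG gave 69.7% ± 1.47 and 59.8% ± 0.30. For ACACTG the relaxed-only peaks were closer, with 65.7% upstream against 71.3% in IDR peaks. On the opposite strand ACACTG reads CAGTGT, which shares CAGTG with ACAGTG. Read on the same strand, CAGTG therefore lay mostly upstream of the summit within ACAGTG and mostly downstream within CAGTGT. Upstream occurrences of ACAGTG within 160 bp had a median offset of -86.5 bp and quartiles of -114.75 and -60.25 bp. Since an even spread over that window would put the median near its middle, the median alone does not place ACAGTG. At 40 to 120 bp upstream, it was followed by G in 53.7% of 1258 occurrences and preceded by C in 40.2% and by T in 36.2%. A summit shifted by the caller would put it on 1 genomic side, but the lower of the shares for the plus and minus strands was 70.8%. Nearby TSSs are not needed, with 71.8% at distal peaks. Exact repeats are not the whole cause, since 99.3% of the IDR peaks lay in unique sequence. Leaving out the others decided nothing, as they were too few to move the share (69.2% over 8367 peaks), and diverged copies of repeats stay open. ACAGTG lay within 100 bp of the summit at 18.7% of promoter and 20.8% of distal peaks among the strongest 2106. The shares were 13.8% and 17.2% among the weakest 2106, and 11.2% of relaxed-only peaks in either class. This window cuts through its most frequent bin at IDR peaks, 80 to 120 bp upstream. Within 160 bp, 449 of the strongest 2106 peaks had it upstream only, 149 downstream only and 46 on both sides. Among the 20304 relaxed-only peaks the counts were 1825, 1396 and 159. An oriented sequence element that includes ACAGTG may therefore mark part of the IDR peaks. This is a hypothesis, found and tested on the same data, and whether topi itself contacts it was not tested.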
